A study of Mus musculus with 2 samples.

How the data were processed

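The data are single-cell 3′ RNA counts and hashtag counts of mouse skin cells of the Sox9-CreER lineage, with 28 and 90 bp reads. The deposited matrix holds a UMI count per feature (gene or hashtag) and barcode, and lists all barcodes rather than called cells. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 7.1.0 against the mm10 build, and Seurat 4.3.0 was used downstream. The authors' processed objects were not used here. The deposited feature reference names the condition of each of the 6 hashtags. Per the labels, unwounded cells were sorted as live, negative for CD140a, CD117, CD31, CD45 and SCA1, and positive for integrin-α6 (high), CD34, CD200 and YFP. Wounded cells were sorted as live, negative for the same first 4 markers, and positive for integrin-α6 (high) and YFP, with no gate on SCA1, CD34 or CD200.

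Barcodes with at least 1000 gene UMIs (9880), at least 500 genes (9829) and at most 10% mitochondrial UMIs were kept, which dropped 2929 for mitochondrial content and left 6900. These held 83.2% of the gene UMIs. Hashtags were assigned with Seurat 5.3.0 (HTODemux, quantile 0.99) in R 4.3.3, giving 5659 singlets, 503 doublets and 738 negatives, and singlets alone were used. Doublets of a single hashtag stay in the pools. Scrublet, set to an expected 8%, called 0 of 6900 barcodes with its automatic threshold. Its score ranked hashtag doublets above singlets with an area under the curve of 0.784, and removing the 126 singlets of highest score, the number of doublets expected within a hashtag, was therefore added as an alternative. Free RNA was estimated from 65043 barcodes with at least 100 and below 400 UMIs (mean 256), whose UMIs would make up 3.21% and 3.28% of the unwounded +/+ and fl/fl pools and between 0.517% and 0.635% of the wounded pools. It was not subtracted in the values reported.

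Cells were clustered together with scanpy 1.11.5 in Python 3.11.15 (counts scaled to 10000 per cell and logged, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster took the name of 1 of 16 cell type lists when at least 3 of its markers were at least 10 CPM and 2-fold above the other cells. The rule was tightened after the data were seen: a name also needs 2 own markers among the 10 top genes, or at least 2 of every 3 of its markers raised, and a cluster stayed unnamed where another class had more markers among those genes, or where its UMI count was low and none of its markers was among them. Cells with at least 2 UMIs of Xist and at most 1 of Y-linked genes were called female, and the reverse male. Sex calls were made after the data were seen.

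For each pool the UMIs of its cells were summed and scaled to the pool total (CPM). Folds are ratios of CPM with exact conditional binomial intervals, levels carry exact Poisson intervals, shares Clopper-Pearson intervals and differences of shares Newcombe intervals (scipy 1.17.1, statsmodels 0.14.6). A count of 3 was the limit that a count of 0 allows. Comparisons were wounded over unwounded within +/+ at 3 and 5 days, and fl/fl over +/+ at each stage, in whole pools and within classes of at least 50 cells in both pools. With 1 pool per condition no test was run, and counts of genes by size of fold describe these pools and call no gene changed. The median log2 fold of each of 28 gene lists, over members of at least 5 CPM, was placed among 10000 random lists of equal size matched in 20 expression bins, for lists of at least 3 measured members.

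The comparisons, filters, gene lists, cell type lists and the rule for which genes to name were set before the data were examined, unlike the final rule that names clusters. Named genes were the 10 highest and 10 lowest log2 folds among genes with a mean of at least 50 CPM whose interval leaves out 0, without mitochondrial, ribosomal, Gm- and Rik-named, Xist, Tsix and Y-linked genes. From each list described, up to 4 members of at least 20 CPM with the largest folds were named, and Phgdh, Psat1, Psph, Atf4, Cd34, Sox9, Krt6a, Krt1 and Mki67 were always given for whole pools. Which lists to describe in the text was decided from their values.

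The calculation was tested on simulated data, with Poisson counts drawn from the joint profile of the pools at 5 days at their own depths. Of 50 genes each set to 1.25-, 1.5-, 2- and 4-fold, 100% were found with the right sign, and the intervals held the true fold for 94%, 98%, 98% and 94% of them. Among 2484 genes with no change 95.1% of intervals held 0. Of 35 lists with no shift, 2 lay outside the central 95% of random lists, and a list shifted by -0.5 was found at -0.49. The simulation covers counting error and not animals.

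Alternatives were other cell filters (2000 UMIs, 5% or 20% mitochondrial), other hashtag calls (MULTIseqDemux for cell numbers, and a rule of at least 20 hashtag UMIs with 70% in the top hashtag), TMM factors (edgeR 4.0.16), equal weight per cell, no minimum CPM, removal of contaminant-like clusters, Leiden resolutions 0.5 and 1.5, clustering without cell cycle genes and cells thinned to 2000 UMIs. Added after the data were seen were male cells alone, fl/fl cells without a Phgdh UMI, the highest Scrublet scores removed, low quality clusters removed, unwounded bulge-like clusters alone, clustering without the stem cell genes and subtraction of free RNA. A list's value counted as called below percentile 2.5 or above 97.5, and a gene's when its interval left out 0 and it was at least 1.25-fold apart. A value was taken as unmoved within the main counting interval of a gene or share, or within the bootstrap interval over the members of a list. These definitions were chosen after the main values were seen but before the alternatives were computed. Figures were drawn with matplotlib 3.10.9, and anndata 0.12.19 and scikit-learn 1.9.0 were also used.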

Results

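The series asks how the enzyme PHGDH, and with it the making of serine, bears on the fate of hair follicle stem cells in resting and injured skin. Single-cell RNA sequencing was done on mouse skin cells in which Sox9-CreER had switched on a YFP reporter, so that YFP marks cells descended from Sox9-expressing cells of the hair follicle. The mice carried either intact Phgdh alleles (+/+) or floxed alleles (fl/fl), which the same Cre deletes. Cells came from unwounded skin and from skin at 3 and 5 days after wounding. The 6 conditions were marked with 6 hashtag antibodies and pooled into a single 3′ capture, so each condition has 1 pool of cells and no replicate. The 2 GEO samples are the gene expression library and the hashtag library of that capture.

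The deposited matrix held 317114087 gene UMIs and 9694124 hashtag UMIs over 32285 genes and 2997303 barcodes. Of these barcodes, 6900 passed the filters for cells and 5659 carried a single hashtag. The +/+ pools held 406 cells (unwounded), 1281 cells (3 days) and 1353 cells (5 days). The fl/fl pools held 662, 523 and 1434 cells at the same stages. Summed over cells, the +/+ pools had 3241223, 54365641 and 54500493 UMIs and the fl/fl pools 5167131, 22247350 and 70925244 UMIs. Unwounded cells were shallower, with a median of 7174.5 UMIs (+/+) and 7243 UMIs (fl/fl) per cell. The medians were 40042 and 39800 at 3 days and 36277 and 45701.5 at 5 days, for +/+ and fl/fl in that order. A count of 3 UMIs, the upper limit that a count of 0 allows, corresponds to 0.926 and 0.581 CPM in the unwounded +/+ and fl/fl pools and to between 0.0423 and 0.135 CPM in the wounded pools. All intervals given are 95% intervals and cover counting error only, not the difference between animals. With 1 pool per condition no test was possible, and "higher" or "lower" describes these pools alone.

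Genes are named by their symbol in the deposited feature table, and positions were matched by that symbol in a GRCm38.p6 gene table, the assembly that the mm10 build of the labels stands for. Phgdh (ENSMUSG00000053398) lies on chromosome 3 from 98313171 to 98339969. Among the other genes described, Cd34 lies on chromosome 1 from 194938821 to 194961292, Krt15 on chromosome 11 from 100131759 to 100135949 and Krt1 on chromosome 15 from 101845426 to 101850786. Of the 219 genes that the naming rule picked, 216 were placed in that table. The labels describe the mice as pooled male and female. Cells with Xist and no more than 1 UMI of Y-linked genes, taken as female, numbered 399 (31.1%) in the +/+ pool at 3 days and 320 (23.7%) in the +/+ pool at 5 days. The other 4 pools held 0 such cells, so each wounded genotype comparison sets a pool of both sexes against a pool in which no female cell was seen.

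Phgdh encodes the first enzyme of serine synthesis and was lower in each fl/fl pool than in the +/+ pool of the same stage. In unwounded skin it stood at 25.2 CPM (21.0 to 29.9) in fl/fl and 54.3 CPM (46.6 to 62.9) in +/+ cells, a log2 fold of -1.11 (-1.45 to -0.77). At 3 days it stood at 15.3 CPM (13.7 to 17.0) against 116.8 CPM (113.9 to 119.7), a log2 fold of -2.93 (-3.09 to -2.77). At 5 days the values were 20.2 CPM (19.2 to 21.3) and 138.3 CPM (135.2 to 141.4), a log2 fold of -2.77 (-2.86 to -2.69). In the unwounded fl/fl pool 5 cells held 56.9% of the 130 Phgdh UMIs. Within the unwounded bulge-like clusters the values were 10.9 and 53.1 CPM, a log2 fold of -2.29 (-2.78 to -1.82). The sources used here do not say which exons are floxed, and 3′ reads can come from a deleted allele, so the remaining level does not measure how many cells lost the gene. The next enzymes of the pathway differed less between genotypes. Psat1 stood at 13.9 (+/+) and 12.4 CPM (fl/fl) in unwounded skin, at 78.6 and 82.7 CPM at 3 days and at 80.4 and 87.8 CPM at 5 days. Psph stood at 40.1 and 39.3 CPM, then 112.5 and 109.8 CPM, then 131.9 and 126.9 CPM.

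**Figure D1:**
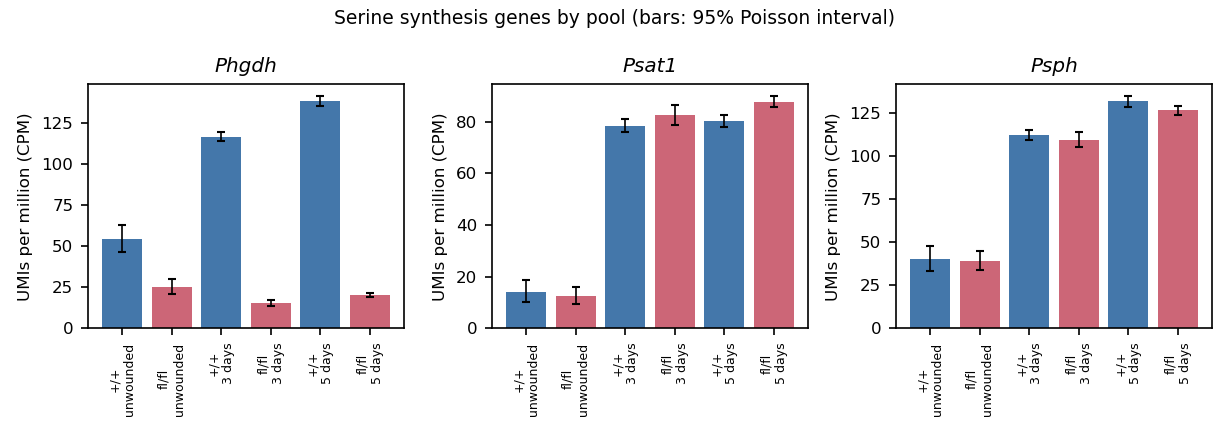
Level in counts scaled to the pool total (CPM) of the 3 serine synthesis genes in each of the 6 pools, with bars for the 95% Poisson interval of the count. Phgdh stood between 15.3 and 25.2 CPM in the fl/fl pools and between 54.3 and 138.3 CPM in the +/+ pools, whereas Psat1 and Psph were higher in the wounded pools of both genotypes than in the unwounded pools.

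The comparison of +/+ cells at 3 days with unwounded +/+ cells asks what the Sox9 lineage expresses in a healing wound. Stem cell genes of the bulge were far lower in the wounded pool, while genes of proliferation, keratinocyte differentiation, inflammation and wound-edge migration were higher. Cd34, the surface marker of bulge stem cells, stood at 20.9 CPM at 3 days and 527.3 CPM in unwounded skin, a log2 fold of -4.66. Lgr5 stood at 19.99 and 733.4 CPM (-5.20), Krt24 at 20.9 and 605.6 CPM (-4.86) and Sox9 at 61.9 and 240.3 CPM (-1.96). The gates differed, since unwounded cells were also selected for CD34 and CD200 and against SCA1, and these folds include that selection. The pools also differed in sex calls, with 0 of 406 unwounded +/+ cells called female against 31.1% at 3 days. Sex, animal and wound are not separated in these folds.

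Of 24 measured genes of hair follicle stem cell identity, 23 were lower at 3 days, with a median log2 fold of -2.53. That median lay at percentile 0 among 10000 random lists matched on expression, which is a description of these libraries and not a test. BMP and quiescence genes had a median of -2.13 with 14 of 15 lower, among them Id2 (20.5 against 320.2 CPM, -3.97), Txnip (-3.94) and Id3 (-2.44). WNT and hedgehog targets had a median of -2.06, with Gli2 at -3.17 and Ptch1 at -2.27. Genes of hemidesmosomes and basement membrane had a median of -1.49, with Dst at -2.77 and Col17a1 at 495.5 against 1406 CPM. The lowest genes by fold were St6galnac5 (0.7 against 194.7 CPM, -8.08), Pdzrn4 (6.2 against 658.7 CPM, -6.73), Kcnma1 (-6.50), Myoc (-6.48), Ltbp2 (-6.43), Grik1 (-6.37), Me3 (-6.16), Ccn2 (13.9 against 967.8 CPM, -6.13), Chat (-5.96) and Tmtc1 (-5.88).

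Cell cycle genes were higher at 3 days, with a median log2 fold of 2.82 over the 20 G2/M genes and 1.57 over the 19 G1/S genes, all of them higher. Top2a stood at 214.4 against 14.8 CPM (3.86), Mki67 at 140.5 against 23.1 CPM (2.60) and Mcm3 at a log2 fold of 2.88. The 16 measured suprabasal differentiation genes were all higher, with a median of 2.53 and Cnfn at 3.68, Calm4 at 3.39, Tgm3 at 3.35 and Krt1 at 1405 against 314.1 CPM (2.16). Wound-edge and migration genes were higher in 29 of 31 cases, with a median of 1.87. The collagenase gene Mmp13 stood at 84.9 against 0.6 CPM (interval of the log2 fold 5.25 to 10.15), Mmp9 at 67.6 against 1.9 CPM (5.19) and the wound keratin gene Krt6a at 6786 against 1365 CPM (2.31). The 10 inflammatory genes had a median of 2.76, with S100a9 at 608.7 against 16.0 CPM (5.25) and S100a8 at 378.4 against 12.3 CPM (4.94). The other highest genes were Crct1 (157.9 against 3.7 CPM, 5.41, 4.61 to 6.37), Lce3c (4.89), Klk7 (4.83), Hist1h1b (4.80), Slpi (4.47), the ligand gene Nrg1 (508.4 against 27.2 CPM, 4.23), Csta3 (4.05) and Il24 (133.4 against 8.3 CPM). The unwounded levels of several of these rest on few cells: 41.7% of the 12 Crct1 UMIs, 48.9% of the 88 Nrg1 UMIs and 52.7% of the 1018 Krt1 UMIs came from single cells. In the wounded +/+ pool the 5 highest cells for each gene held 49.9% of the Crct1 and 72.9% of the Lce3c UMIs.

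Metabolic genes and stress genes were higher as well. Glycolysis genes were higher in 14 of 15 cases (median 1.79), with the lactate transporter gene Slc16a3 at 2.69, Pgk1 at 459.1 against 90.4 CPM (2.34) and Eno1 at 2.26. Hypoxia genes had a median of 1.38, with Vegfa at 65.4 against 8.9 CPM (2.87) and Egln3 at 2.02. The serine synthesis genes were all higher, with Psat1 at 78.6 against 13.9 CPM (interval of the log2 fold 2.08 to 2.96), Psph at 1.49 (1.24 to 1.75) and Phgdh at 1.10 (0.89 to 1.33). Targets of ATF4, the transcription factor of the integrated stress response, were higher in 13 of 16 cases (median 1.18), with Eif4ebp1 at 2.07, Cebpb at 1.87, Nupr1 at 1.80 and Asns at 70.3 against 21.6 CPM (1.70). Atf4 itself was higher by less, at 125.9 against 73.7 CPM (0.77, 0.59 to 0.96). Aminoacyl-tRNA synthetase genes were higher in 17 of 18 cases (median 0.99), with Gars at 100.5 against 35.5 CPM and Vars at 1.24. Amino acid transporters split, with Slc6a14 at 5.88 and Slc7a1 at 2.04 but Slc38a2 at 323.5 against 726.3 CPM (-1.17). The 15 cholesterol synthesis genes were all higher (median 1.21), with Fdps at 1.90 and Sqle at 1.89. The unfolded protein response had a median of 0.96, with Manf at 1.59 and Hspa5 at 1.15. Tight junction and desmosome genes had a median of 0.65, with Cldn4 at 1.84 and Pkp1 at 1.59.

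Immediate early genes, which cell dissociation also induces, had a median of -0.69 at 3 days (11 of 14 lower), with Btg2 at -1.64, Fosb at -1.59 and Jun at -1.43. With TMM factors, a scaling that discounts the most unequal genes, the log2 folds of genes of at least 50 CPM were higher by a median of 0.56 at 3 days and 0.59 at 5 days. By size alone, 426 of the 3183 genes of at least 50 CPM were 2-fold or more higher at 3 days and 658 were 2-fold or more lower.

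At 5 days the same question was asked of +/+ cells against the unwounded pool, with the same difference in gates. The sex calls differed here too, with 23.7% of the cells at 5 days and 0 unwounded cells called female. The stem cell identity list had a lower median than at 3 days, and differentiation genes were again higher than in unwounded cells. Cd34 stood at 7.3 CPM against 527.3 CPM (-6.18), Sox9 at 71.0 against 240.3 CPM (-1.76), and 23 of 24 stem cell identity genes were lower, with a median of -3.27 and Fgf18 at -6.25, Igfbp5 at -5.82 and Krt24 at -5.49. Krt1 stood at 2929 CPM (3.22), and filaggrin (Flg) at 53.5 against 1.9 CPM (4.85). The 16 differentiation genes were all higher with a median of 2.36.

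The lowest genes at 5 days were Myoc (0.5 against 141.0 CPM, -8.26), St6galnac5 (-7.65), Pdzrn4 (-7.28), Ltbp2 (-6.84), Chat (-6.65), Adcy1 (-6.37), Me3 (-6.35), Camk4 (-6.23), Ccn2 (-6.23) and Grik1 (-6.23). The highest were Hist1h1b (210.8 against 8.3 CPM, 4.66), Defb1 (128.6 against 8.6 CPM, 3.90), Nrg1 (399.6 against 27.2 CPM, 3.88), Slpi (3.86), Top2a (200.7 against 14.8 CPM, 3.76), Calm4 (1149 against 86.7 CPM, 3.73), Stfa3 (3.57), Sprr2a3 (3.55), S100a9 (181.9 against 16.0 CPM, 3.50) and Rbp2 (3.45). In the unwounded pool single cells held 48.9% of the Nrg1 UMIs and 39.5% of the Calm4 UMIs. All 14 measured BMP and quiescence genes were lower (median -2.20), with Id2 at -4.89 and Nfatc1 at 26.8 against 174.9 CPM (-2.71). All 20 G2/M genes were higher (median 2.69), with Mki67 at 133.1 against 23.1 CPM (2.52). Wound-edge genes were higher in 27 of 30 cases (median 1.57), with Krt6a at 6483 against 1365 CPM (2.25), Epgn at 2.85 and Krt6b at 2.68. Interferon response genes had a median of 0.47, with the chemokine gene Cxcl10 at 38.8 against 1.5 CPM (4.65) and Irf1 at 2.72.

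Serine synthesis genes were again higher than in unwounded +/+ cells, with Psat1 at 2.53 (2.11 to 2.99), Psph at 1.72 (1.47 to 1.98) and Phgdh at 1.35 (1.13 to 1.57). ATF4 targets were higher in 12 of 16 cases (median 1.09), with Nupr1 at 2.22 and Asns at 1.63, and Atf4 itself stood at 0.74. All 18 aminoacyl-tRNA synthetase genes were higher (median 0.86). Glycolysis genes were higher in 14 of 15 cases (median 1.69, Eno1 at 2.23), hypoxia genes had a median of 1.13 (Vegfa at 2.37) and the 15 cholesterol synthesis genes a median of 1.24 (Sqle at 1.90). Among amino acid transporters Slc7a1 was higher (1.93) and Slc38a2 (-1.41) and Slc3a2 (-1.02) were lower. Immediate early genes had a median of -0.48 with plain totals and 0.10 with TMM factors, so their direction at 5 days rests on the scaling.

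**Figure D2:**
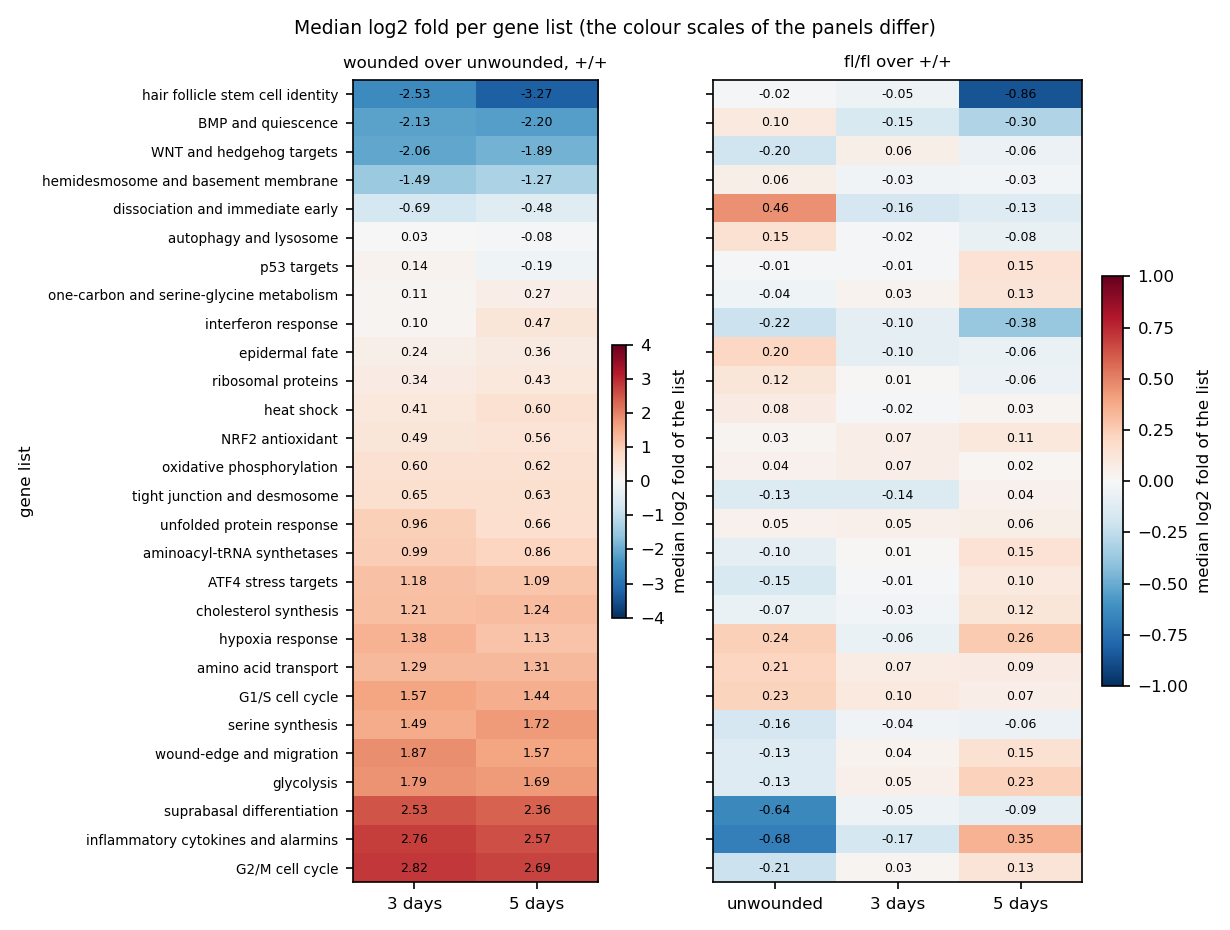
Median log2 fold of the members of each of 28 gene lists, for +/+ cells at 3 and 5 days over unwounded +/+ cells (left) and for fl/fl over +/+ cells at each stage (right), on different colour scales. Stem cell identity genes had medians of -2.53 and -3.27 in the wounded pools and of -0.86 in fl/fl over +/+ at 5 days, and with TMM factors the wound values would be higher by a median of 0.56 and 0.59, which turns the immediate early list at 5 days from -0.48 to 0.10.

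The genotype comparison in unwounded skin asks whether resting stem cells differ when Phgdh is deleted. The 2 pools were close, with 98.4% of 3270 genes within 1.5-fold. Immediate early genes were higher in fl/fl cells in 14 of 14 cases, with a median log2 fold of 0.46 (percentile 100): Fos stood at 2911 against 1930 CPM (0.59), Junb at 0.58 and Egr1 at 0.55. Stem cell identity genes showed a median of -0.02, and Cd34 stood at 534.1 CPM in fl/fl and 527.3 CPM in +/+ cells (0.02), while Sox9 stood at 191.0 against 240.3 CPM (-0.33). Mki67 stood at -0.30 (-0.75 to 0.15) and Krt6a at 815.7 against 1365 CPM (-0.74). ATF4 targets had a median of -0.15 (percentile 9.11), aminoacyl-tRNA synthetases one of -0.10, and Atf4 itself stood at 86.1 against 73.7 CPM (0.22, -0.01 to 0.46).

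The highest genes in unwounded fl/fl cells were Rhob (86.3 against 40.4 CPM, 1.09), Homer1 (97.9 against 47.2 CPM, 1.05), the transcription factor gene Klf2 (100.1 against 49.1 CPM, 1.03), Chsy3 (0.87), Fam71a (0.85), Angptl7 (0.85), Azin1 (0.77), Glul (0.74), Sertad1 (0.73) and Dusp1 (564.3 against 346.8 CPM, 0.70). The lowest were Gsta4 (20.1 against 130.2 CPM, -2.69), Sprr1b (78.6 against 326.1 CPM, -2.05), Sprr1a (-2.03), Spink5 (-1.92), Krt6b (182.9 against 539.6 CPM, -1.56), Krt16 (587.0 against 1647 CPM, -1.49), Lypd3 (-1.46), Ly6d (-1.45), Sox5 (42.2 against 84.2 CPM) and Fabp5 (-0.97). Apart from Sox5, the UMIs of these genes in the +/+ pool lay mostly in 14 cells outside the bulge-like clusters, which held between 69.96% and 84.3% of each gene's UMIs. The highest +/+ cell for each gene held 79.4% of the Sprr1a, 74.2% of the Gsta4, 63.2% of the Krt6b and 51.5% of the Krt16 UMIs. Within the bulge-like clusters Krt16 had a log2 fold of 0.00, Krt6b of -0.03, Sprr1b of -0.12 and Gsta4 of -0.83, while Sox5 stayed at -1.01. With the stricter hashtag rule Krt16 stood at 0.24 and Sprr1b at 0.45. Markers of the upper hair follicle (median -0.60) and of wound-edge cells (-0.72) were also lower in the whole fl/fl pool, and the wound-edge markers stood at 0.12 within the bulge-like clusters. Krt1 was higher in fl/fl (440.5 against 314.1 CPM, 0.49), with 39.9% of its fl/fl UMIs in 1 cell. Within the bulge-like clusters immediate early genes kept a median of 0.41 (13 of 14 higher), and 21 of 24 stem cell identity genes were lower, with a median of -0.12.

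At 3 days the comparison asks whether Phgdh deletion alters what the lineage expresses early in the wound. Krt1, Krt10 and upper follicle genes were lower in fl/fl cells, and the medians of stem cell and stress lists stayed close to 0. Krt1 stood at 720.9 against 1405 CPM (-0.96), Krt10 at 574.8 against 1178 CPM (-1.04), Krt79 at 144.1 against 310.3 CPM (-1.11) and Cst6 at 289.9 against 786.0 CPM (-1.44). Markers of suprabasal cells had a median of -0.76, while the longer suprabasal differentiation list had one of -0.05 over all cells and 0.09 over male cells, and markers of the upper hair follicle one of -0.23. Stem cell identity genes had a median of -0.05, with Cd34 at 25.3 against 20.9 CPM (0.28) and Sox9 at 46.0 against 61.9 CPM (-0.43). ATF4 targets had a median of -0.01 (percentile 52.2), aminoacyl-tRNA synthetases one of 0.01, and Atf4 stood at 128.2 against 125.9 CPM (0.03), Krt6a at 0.10 and Mki67 at -0.02.

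The highest genes at 3 days were the metalloproteinase gene Mmp10 (87.6 against 37.8 CPM, 1.21, 1.12 to 1.30), Lce3c (0.88), Slpi (0.59), Postn (279.2 against 206.5 CPM, 0.43), Upp1 (0.43), Klk10 (0.42), Crct1 (0.42), Phlda1 (0.38), Mid1 (0.36) and Il24 (0.35). The highest fl/fl cell for each gene held 79.0% of the Lce3c, 52.1% of the Crct1 and 47.3% of the Slpi UMIs of the pool. Whether it was the same cell was not examined. With up to 20% mitochondrial UMIs allowed, Lce3c, Crct1 and Slpi stood at -1.36, -0.65 and -0.42. The 5 highest fl/fl cells for each gene held 42.2% of the Mmp10, 55.9% of the Mt4 and 57.2% of the Defb6 UMIs of the pool. For Krt1, Krt10 and Krt79 they held 39.9%, 39.3% and 42.3%. The intervals do not cover which cells were drawn. Below Phgdh, the lowest genes were Mt4 (24.0 against 91.9 CPM, -1.94), Cst6, Defb6 (86.9 against 230.4 CPM, -1.41), Krt79, Krt10, Krt1, Cldn1 (-0.77), Calm4 (-0.76) and Chit1 (-0.70). Among male cells alone Krt10 stood at -0.55 and Krt1 at -0.54, each nearer 0 than in the whole pools, whereas Cst6 stood at -1.38 and Mmp10 at 1.40. Immediate early genes were lower in 13 of 14 cases (median -0.16), with Nr4a1 at -0.44, Btg2 at -0.40 and Egr1 at -0.36. All 18 oxidative phosphorylation genes were slightly higher (median 0.07, Cox7a2 at 0.23). Tight junction and desmosome genes were lower in 11 of 14 cases (median -0.14), with Dsg1a at -0.54. Inflammatory genes went both ways, with Il33 at -0.52 and Cxcl1 at 0.50. By size, 1 of 2836 genes was 2-fold or more higher and 8 were 2-fold or more lower.

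At 5 days the comparison asks the same of the later wound, and stem cell genes of the hair follicle were lower in fl/fl cells. All 21 measured identity genes were lower, 13 of them by 1.5-fold or more, with a median log2 fold of -0.86 (percentile 0). Krt15 stood at 241.7 against 566.0 CPM (-1.23, -1.25 to -1.20), Postn at 44.1 against 103.2 CPM (-1.23), Ptn at 54.9 against 120.1 CPM (-1.13), Cd34 at 3.6 against 7.3 CPM (-1.01), Sfrp1 at -0.90 and Sox9 at 50.8 against 71.0 CPM (-0.48). Glycolysis and hypoxia genes were modestly higher, and interferon response genes lower. Among male cells alone the identity genes had a median of -0.49, with Krt15 at -0.81, Postn at -0.81 and Cd34 at -0.71.

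The highest genes were the galectin gene Lgals1 (224.5 against 130.5 CPM, 0.78, 0.74 to 0.82), the metallothionein gene Mt4 (249.5 against 156.4 CPM, 0.67), Stfa2 (0.57), the cathepsin gene Ctsl (268.9 against 189.1 CPM, 0.51), Ptprz1 (0.48), S100a8 (153.4 against 111.2 CPM, 0.46), Anxa3 (0.45), Ero1l (0.44), Mid1 (0.43) and Sprr2a3 (0.42). Below Phgdh, the lowest were Defb6 (24.8 against 92.8 CPM, -1.90), Ccl27a (ENSMUSG00000073888, 29.4 against 73.2 CPM, -1.32), Adgrl3 (-1.23), Krt15, Postn, Krt79 (81.2 against 187.8 CPM, -1.21), Tmem45a (-1.16), Clca3a2 (-1.16) and Slco3a1 (-1.14). All 9 were higher in female than in male +/+ cells, and among male cells Defb6 stood at -0.58, Ccl27a at -0.21, Clca3a2 at -0.38 and Krt79 at -0.63. The 10 highest genes moved less, with a median of 0.47 over all cells and 0.44 over male cells. For Defb6 the 5 highest cells of each pool held 64.9% of the fl/fl and 44.7% of the +/+ UMIs. Krt1 stood at 2164 against 2929 CPM (-0.44), Krt6a at 0.20 and Mki67 at 0.13.

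Stress and metabolic lists differed by small amounts at 5 days. These values cover all cells, and female cells were seen in the +/+ pool only. Female +/+ cells were lower than male ones in all glycolysis and G2/M genes measured, as given among the other observations. The values of both lists include that difference. Among male cells Mki67 stood at 0.04, against 0.13 over all cells. ATF4 targets were higher in fl/fl cells in 11 of 15 cases (median 0.10, percentile 98.8), with Ddit4 at 0.34, Nupr1 at 0.21 and Asns at 0.20, and Atf4 stood at 142.4 against 123.3 CPM (0.21, 0.16 to 0.25). All 18 aminoacyl-tRNA synthetase genes were higher (median 0.15, Iars at 0.28 and Nars at 0.20). Glycolysis genes were higher in 13 of 15 cases (median 0.23), with Slc16a3 at 0.37, Slc2a1 at 0.30 and Ldha at 0.29. Hypoxia genes were higher in 10 of 12 cases (median 0.26), with Bnip3 at 0.34. Wound-edge genes were higher in 22 of 31 cases (median 0.15), with Hmga2 at 0.77 and Mmp13 at 0.58, and inflammatory genes in 10 of 13 (median 0.35), with S100a9 at 0.38 and Ptgs2 at 0.35. The 20 G2/M genes had a median of 0.13, and the 15 cholesterol synthesis genes one of 0.12 (Msmo1 at 0.26). Without the fl/fl cells that had a Phgdh UMI the G2/M median was -0.04. That filter acts on fl/fl cells alone, where Phgdh stood at 28.7 CPM in cycling and 11.1 CPM in suprabasal cells. It also took the difference in the cycling share from 2.20 to 0.245 points, so this median cannot be read apart from the mix of cells left. Interferon response genes were lower in 9 of 10 cases (median -0.38), with B2m at 96.7 against 161.2 CPM (-0.74) and H2-K1 at -0.56. BMP and quiescence genes had a median of -0.30, with Nfatc1 at 14.7 against 26.8 CPM (-0.86). Weighting each cell equally turned S100a8 to -0.05 and S100a9 to -0.08.

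**Figure D3:**
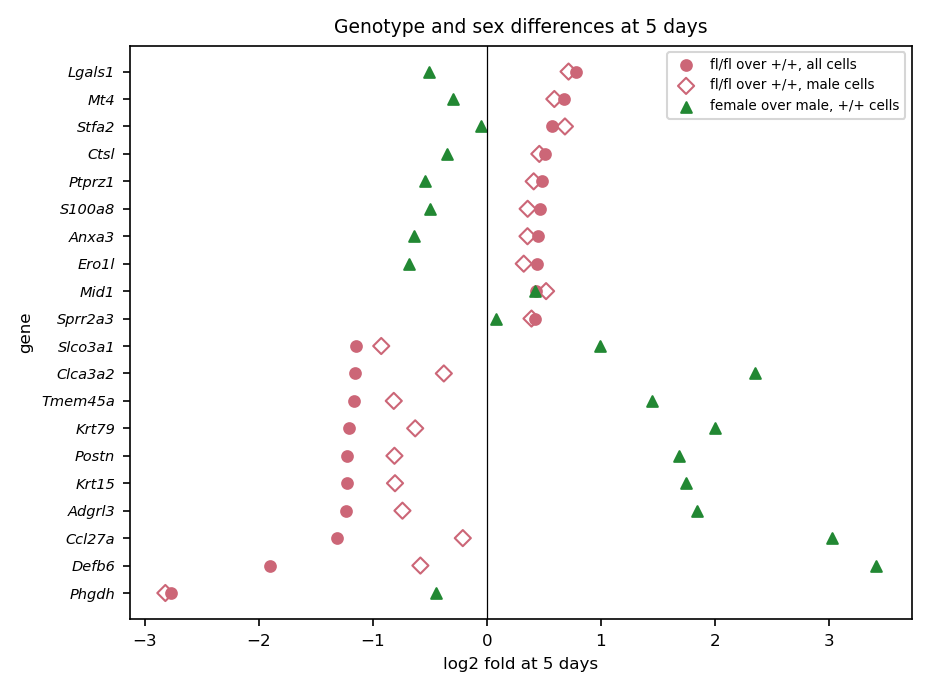
Log2 folds at 5 days of the 10 highest and 10 lowest genes of the genotype comparison, for all cells (filled circles), male cells alone (hollow diamonds) and female over male +/+ cells (triangles). Defb6, at -1.90 over all cells and -0.58 over male cells, stood at 3.42 in female over male +/+ cells, while Phgdh stood at -2.77 over all cells.

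Clusters were named by marker genes, and the shares of cells in them ask which states the lineage takes up. Bulge-like cells made up 96.6% (94.3 to 98.1) of unwounded +/+ and 96.7% (95.01 to 97.9) of unwounded fl/fl cells, as the CD34 and CD200 gate of the unwounded sort selects. In the wounds, sorted without CD34 or CD200, they made up 13.8% (12.0 to 15.8) of +/+ and 15.7% (12.7 to 19.1) of fl/fl cells at 3 days. At 5 days they made up 10.9% (9.26 to 12.6) of +/+ cells, 147 of 1353, and 3.56% (2.66 to 4.65) of fl/fl cells, 51 of 1434. That difference was -7.31 percentage points (Newcombe interval -9.27 to -5.41) over all cells and -4.68 points (-6.75 to -2.81) over male cells. With cells thinned to 2000 UMIs, where fewer cells carried the class name, the shares were 2.39% and 0.774% and the difference -1.62 points (-2.69 to -0.675). Unwounded bulge-like cells lay mainly in clusters 9, 17 and 19, and wounded ones mainly in cluster 16, whose top genes were Sfrp1, Postn and Shisa2. Cluster 16 also held 2 unwounded +/+ and 7 unwounded fl/fl cells.

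Suprabasal differentiating cells, marked by Krt1 and Krt10, made up 9.21% (7.68 to 10.9) of +/+ and 5.16% (3.43 to 7.42) of fl/fl cells at 3 days, a difference of -4.05 points (-6.38 to -1.37). Among male cells the difference was -2.31 points (-5.16 to 0.808). At 5 days their shares were 22.0% and 21.3%. Cycling cells made up 17.4% (+/+) and 19.1% (fl/fl) at 3 days and 15.4% and 17.6% at 5 days. The 5-day difference of 2.20 points (-0.570 to 4.95) depended on the alternative, at 6.14 points (3.36 to 8.92) with the stricter hashtag rule, 6.94 after thinning and -1.83 (-5.26 to 1.53) among male cells. At Leiden resolution 0.5 the 3-day shares were 2.03% and 2.68%. Among the 406 unwounded +/+ cells 0 lay in these clusters (upper limit 0.904%), while the clustering of thinned cells placed 3 there. Upper hair follicle cells, marked by Krt79 and Defb6, made up 6.17% and 3.44% at 3 days and 3.33% and 1.88% at 5 days. The differences were -2.73 and -1.44 points over all cells. Among male cells they were -2.51 points (-4.84 to 0.0656) at 3 days and -1.04 points (-2.47 to 0.208) at 5 days. The upper hair follicle shares depended on the clustering too, with 0 cells so named at Leiden resolution 0.5, 6.06% and 4.81% at 5 days at resolution 1.5, and 5.77% and 1.55% after thinning. Wound-edge cells made up 6.40% and 8.03% at 3 days and 0.887% and 0.628% at 5 days. The wound-edge shares at 3 days were 31.9% and 37.7% at Leiden resolution 0.5, a difference of 5.82 points against 1.63 points (-0.884 to 4.54), and 33.6% and 38.8% after thinning, a difference of 5.25 points (0.342 to 10.3). Those at 5 days were 26.6% and 32.5% at Leiden resolution 0.5, a difference of 5.89 points, and 18.0% and 27.1% with at least 2000 UMIs, a difference of 9.17 points (5.99 to 12.3). These alternatives do not measure the same class. At Leiden resolution 0.5 the name covered 1128 cells with only Krt6a, Krt6b and Krt16 raised, beside 309 cells with Mmp9 and Mmp13 raised. Similar keratin clusters took the name after thinning (683 cells) and with at least 2000 UMIs (552 cells). The main run left such a cluster unnamed. Clusters that no class named held 1.72% (+/+) and 1.51% (fl/fl) of unwounded cells, 46.6% and 48.2% at 3 days and 47.3% and 54.8% at 5 days, so the class shares leave out much of the wounded pools. The largest of these expressed Nrg1 and Hmga2 (cluster 4), Krt16 (cluster 3), S100a8, Sprr1b and Il33 (cluster 0) or Lrig1, Lgr6 and Apoe (cluster 12). Cluster 12, with sebaceous as its closest class, held 119 of 1281 +/+ and 47 of 523 fl/fl cells at 3 days. At 5 days it held 136 of 1353 and 59 of 1434, so a lower fl/fl share was not particular to bulge-like cells. At Leiden resolution 1.5 a cluster named sebaceous held 119 +/+ and 56 fl/fl cells at 5 days. A cluster of 13 cells carried melanocyte markers, with Dct at 4364 CPM, and also immune genes, with Cxcl2 at 2529 CPM, Il1b at 1720 CPM and Pf4 at 1469 CPM, so it mixes cells that the gates on CD117 and CD45 should remove. Fibroblast, immune and endothelial lists named no cluster.

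**Figure D4:**
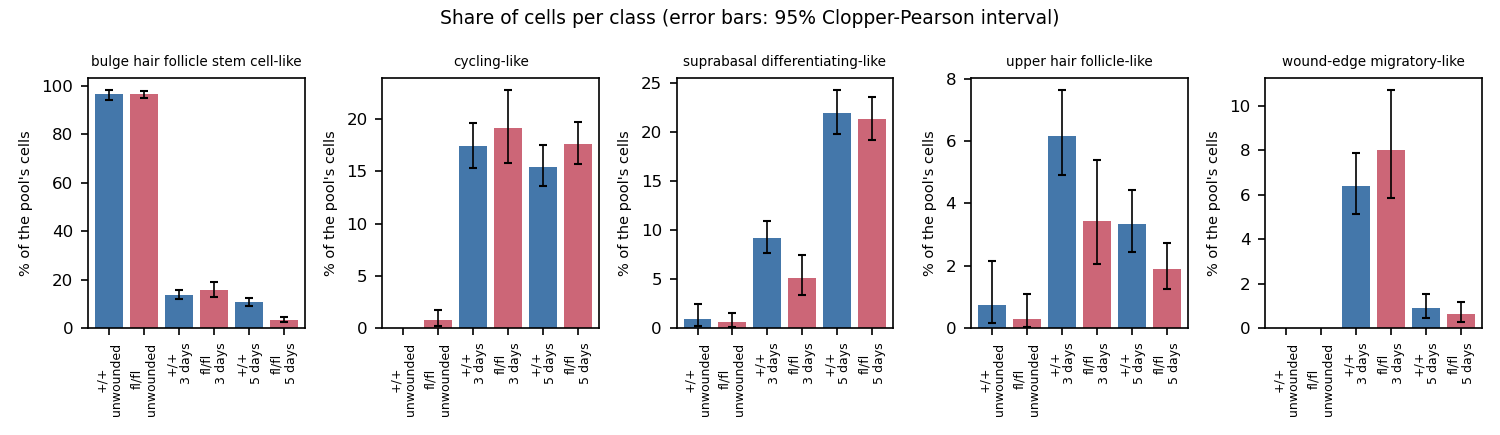
Share of each pool's cells in each named class, in percent, with bars for the 95% Clopper-Pearson interval. Bulge-like cells made up 96.6% and 96.7% of the unwounded pools and 10.9% (+/+) and 3.56% (fl/fl) of the pools at 5 days.

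Comparing genotypes within a class asks which differences hold among cells of the same class, although a class can join several clusters. Phgdh was lower in fl/fl cells in each class compared, at 10.3 against 95.9 CPM (-3.21) in bulge-like and 15.9 against 186.0 CPM (-3.55) in cycling cells at 3 days. At 5 days it stood at 21.1 against 98.97 CPM (-2.23) in bulge-like, 28.7 against 197.2 CPM (-2.78) in cycling and 11.1 against 112.0 CPM (-3.34) in suprabasal cells. Within the 51 fl/fl and 147 +/+ bulge-like cells at 5 days the stem cell identity genes had a median of -0.05, or -0.20 with the stricter hashtag rule, and Cd34 stood at 0.16 (-0.21 to 0.52). Such genes name the class, so values near 0 are partly set by the naming. Cell cycle genes were lower within these cells, with medians of -0.85 (G1/S, 17 of 18 lower) and -0.83 (G2/M, 16 of 19 lower), but Mki67 stood at 70.3 against 69.3 CPM (0.02, -0.47 to 0.49), and Tnc at -1.41. The highest gene was Cxcl10, with 85 UMIs in fl/fl and 3 in +/+ cells, and the lowest was Stxbp5l, with 1 and 259 UMIs. Of the 147 +/+ cells 59 were female, and Stxbp5l stood at 1.97 in female over male +/+ cells at 5 days. Sex, animal and wound are not separated here. At 3 days G2/M genes were lower in fl/fl bulge-like cells in 19 of 20 cases (median -0.53), with Hist1h1b at -1.82, and Stfa3 was higher (0.94).

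In cycling cells at 5 days interferon response genes were lower in fl/fl in 10 of 10 cases (median -0.87), with Irf1 at 39.4 against 90.0 CPM (-1.19), and cholesterol synthesis genes were higher in 14 of 15 (median 0.27). This class joins clusters 1 and 6, which held 190 and 63 fl/fl but 104 and 105 +/+ cells, so these values include a difference in the mix of clusters. Sostdc1, an inhibitor of BMP and WNT signalling, stood at 54.9 against 183.3 CPM (-1.74), Apoe at 840.6 against 1878 CPM (-1.16), Krt15 at -1.09 and Lgals1 at 0.93. In cycling cells at 3 days Ereg was higher (0.72) and Krt15 lower (-1.20). In suprabasal cells at 5 days filaggrin (Flg) stood at 48.0 against 230.0 CPM (-2.26), Mt4 at 0.94 and Mt2 at 0.88, and G2/M genes were higher in 13 of 14 cases (median 0.40). The suprabasal class joins cluster 7, with Mt4 as top gene, and cluster 8, with Flg as top gene. These held 217 and 89 fl/fl but 189 and 108 +/+ cells, so the suprabasal values also include a difference in the mix of clusters. Suprabasal differentiation genes were lower there in 13 of 16 cases (median -0.27). ATF4 targets had medians of 0.07 in cycling and 0.11 in suprabasal cells at 5 days.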

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

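All tests of explanations given here were chosen only after the results were seen, and the test of depth is the last of 3 forms, each seen before the next was chosen. Bulge-like cells made up 3.56% of fl/fl and 10.9% of +/+ cells at 5 days. Female cells, seen only in the +/+ pool, argue for part of this at most, since the difference among male cells was -4.68 percentage points (-6.75 to -2.81; 37 of 1304 fl/fl and 67 of 891 +/+ cells). Unequal depth is argued against as the whole cause, although the cluster compared was not purely bulge-like. Each cell was thinned to 2000 UMIs. The cluster that then held 78.7% of the 3-day bulge-like cells held 45 of 1422 fl/fl and 122 of 1213 +/+ cells at 5 days. That difference was -6.89 points (-8.88 to -5.01). The marker rule left this cluster unnamed, with cycling as its closest class. At full depth 73.3% of its fl/fl and 70.5% of its +/+ cells at 5 days were bulge-like. The class as named after thinning differed by -1.62 points (-2.69 to -0.675). A difference between animals or wounds cannot be told apart from the genotype, because each genotype has 1 pool, the animals per pool are not given in the sources used here, and female and male +/+ cells differed by 10.9 points (6.60 to 15.8) at 5 days, against 1.79 points (-2.36 to 6.26) at 3 days. A loss of bulge-like cells where Phgdh is deleted, the biological explanation that the design names, may contribute and stays untested.

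Phgdh UMIs remained in the fl/fl pools, at 25.2 CPM in unwounded skin, 15.3 CPM at 3 days and 20.2 CPM at 5 days. With the share of free RNA taken from barcodes with at least 100 and below 400 UMIs, free RNA would give up to 11.5% of the level of a fl/fl pool. The Phgdh level of free RNA was taken from barcodes under 100 UMIs (88.2 CPM). This is an estimate and not a limit: the first estimate of free RNA, which was not used, came to 60.1% or more of each pool and would allow the whole level. Were the UMIs from +/+ cells that carry a fl/fl hashtag, drawn evenly from the +/+ pools, at least 21.4 female cells would be needed at 3 days and 49.6 at 5 days, while 0 were seen in either pool (upper limit 3). A minority of cells that kept a working allele may account for much of the level: 43 fl/fl cells at 5 days had 10 or more Phgdh UMIs and held 45.5% of them, against a mean of 0.831 such cells (0 to 3) when the UMIs of +/+ cells were thinned evenly to the fl/fl level. In that pool 75.1% of cells had no Phgdh UMI, against 50.7% under even thinning, and reads from deleted alleles stay open for the rest.

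Wound keratin and cornified envelope genes were lower in the fl/fl than in the +/+ unwounded pool. A few cells outside the bulge-like clusters of the +/+ pool, 14 cells with 12.8% of its UMIs, may account for much of this. The highest cell for each gene held 79.4% of the pool's Sprr1a, 74.2% of its Gsta4 and 51.5% of its Krt16 UMIs. Within the bulge-like clusters the median log2 fold of the 10 lowest genes was -0.0553. Exceptions whose intervals left out 0 were Sox5 (-1.01), Gsta4 (-0.83), Lypd3 (-0.37) and Fabp5 (-0.08). Whether those 14 cells were wounded cells that carried an unwounded hashtag cannot be told apart from cells of the unwounded skin. Of them 7 (50%) passed the stricter hashtag rule, against 254 of 392 (64.8%) of the bulge-like cells. Their median of 23601.5 UMIs against 7129 and median top-hashtag share of 66.4% against 78.2% would go with wounded cells. However, 0 of the 14 were called female, against 31.1% and 23.7% of the +/+ cells at 3 and 5 days. The wounded fl/fl pools also held 0 female cells, and 14 cells are too few to decide. No biological explanation of these 14 cells was tested.

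Several genes had genotype differences of opposite direction at 2 stages, with each interval leaving out 0, the log2 folds at least 1 apart and each of the 4 counts above 3; the differences between stages were not tested. The requirement on the counts was set after the values were seen and left out 1 gene, Mmp10 at 5 days against unwounded skin. The values that follow are the log2 fold of fl/fl over +/+ at the later stage minus that at the earlier stage. For 3 days minus unwounded skin the difference was positive for Gsta4 (2.99), Klk10 (2.83), Sprr1b (2.29), Sprr1a (2.14), Krt16 (1.64), Krt6b (1.59), Lypd3 (1.59), Ly6d (1.58) and Fabp5 (1.02), and negative for Mt4 (-3.66), Angptl7 (-2.10), Krt1 (-1.45), Homer1 (-1.38) and Glul (-1.34). For 5 days minus unwounded skin it was positive for Gsta4 (2.76), Klk10 (2.51), Sprr1b (2.23), Sprr1a (2.06), Spink5 (2.04), Stfa2 (1.68), Krt16 (1.64), Krt6b (1.60), Lypd3 (1.59), Ly6d (1.59), Fabp5 (1.17) and Anxa3 (1.16). It was negative there for Angptl7 (-2.79), Chsy3 (-1.99), Fam71a (-1.79), Glul (-1.66), Klf2 (-1.61), Homer1 (-1.48) and Krt15 (-1.37). Several of these genes had low levels in the wounds, on which their direction there rests. At 5 days Angptl7 stood at 0.39 (fl/fl) and 1.5 CPM (+/+), and Chsy3 at 2.6 and 5.7 CPM. Fam71a stood at 4.4 and 8.4 CPM and Glul at 6.2 and 11.7 CPM. Klf2 (21.6 and 32.3 CPM), Homer1 (35.0 and 47.0 CPM) and Krt15 (241.7 and 566.0 CPM) were higher. At 3 days Angptl7 stood at 0.76 and 1.8 CPM and Glul at 4.8 and 7.3 CPM. For 5 days minus 3 days the difference was 2.61 for Mt4, -1.66 for Postn, -1.44 for Mmp10, -1.29 for Cd34 and -1.27 for Lce3c. The opposite directions of Mt4 and Krt1 at 3 days against unwounded skin end without the fl/fl cells that had a Phgdh UMI, where unwounded skin gave -0.94 and -0.53, and that of Lce3c ends where its 3-day fold stood at -1.47 (the same cells left out) or -1.36 (up to 20% mitochondrial UMIs). Leaving out cells with a Phgdh UMI changes the fl/fl pools alone, so it can also change the mix of cells compared. Within the unwounded bulge-like clusters the directions of Krt16, Krt6b, Ly6d, Spink5, Sprr1a and Sprr1b were no longer opposite or their intervals held 0, those of Lypd3 (-0.37) and Fabp5 (-0.0807) were less than 1 from the wounded folds, and so was Gsta4 (-0.83) at 5 days. Klk10, Stfa2 and Anxa3 were not examined in that way. Cells that express Xist, a signal outside the comparisons of genotype and stage, numbered 399 in the +/+ pool at 3 days and 320 in the +/+ pool at 5 days.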

How the results depend on the processing

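The alternatives with male cells only, with fl/fl cells that had a Phgdh UMI removed, with stem cell genes left out of clustering, with the highest Scrublet scores removed, with low quality clusters removed, with free RNA subtracted and with unwounded bulge-like clusters only were chosen only after results were seen. Removal of fl/fl cells with a Phgdh UMI leaves the +/+ pools untouched, so its values can include a changed mix of fl/fl cells. No paired analysis was possible because each condition has 1 pool of cells and no numbering links the pools. The alternatives that need replicate pools gave no value, Scrublet's automatic call removed 0 of 6900 barcodes, and the first estimate of free RNA from genes of sort-excluded cell types came to between 60.1% and 100% of each pool's RNA and was not used. Of 4428 gene values under alternatives 32 turned a called value to the other sign, of 2353 list values 18 and of 1484 values within classes 16. These totals include values not called in the main run, which by definition could not turn. Called or not, 60 gene values, 120 list values and 193 values within classes changed sign. A further label, moved without such a turn, fell to 1209, 175 and 110 of them. Of the shares 87 of 220 moved, and of their differences 18 of 110. The lower Phgdh in fl/fl kept its direction in all 14 of its values. Over the alternatives that gave it, the stem cell identity list at 5 days in fl/fl over +/+ ranged from -0.90 to -0.49. In the wound comparisons TMM factors added a median of 0.56 (3 days) and 0.59 (5 days) to the log2 folds. The cause was not tested for any value below, except where fewer cells or another scaling are the alternative itself. Depth limits the unwounded pools most, where 3 UMIs stand for 0.926 CPM in +/+ cells.

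Cell numbers moved with the filters. At most 5% mitochondrial UMIs left 213 unwounded and 837 5-day +/+ cells and 339 unwounded fl/fl cells, at most 20% gave 623 unwounded +/+ cells, and the rule on the top hashtag's share gave 267. Phgdh in fl/fl over +/+ moved to -2.67 at 5 days with at least 2000 UMIs, and to -2.10 in unwounded skin with equal weight per cell. With the hashtag share rule it stood at -1.65 in unwounded skin, -2.73 at 3 days and -2.67 at 5 days. The difference in the bulge-like share at 5 days was -1.62 points after thinning, where fewer wounded cells carried the class name, and -4.68 points among male cells. The stem cell identity list stood at -1.97 (TMM) and -2.09 (equal weight) in the wound at 3 days, and at 0.0371 (TMM) in fl/fl over +/+ in unwounded skin. Within bulge-like cells it stood at -0.25 (3 days) and -0.20 (5 days) with the hashtag share rule, and at -0.17 (3 days) with the highest Scrublet scores removed.

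In unwounded fl/fl over +/+, called values changed sign as follows. With the hashtag share rule Sprr1a stood at 2.81, Spink5 at 0.88, Krt6b at 0.59, Sprr1b at 0.45, Fabp5 at 0.43, Ly6d at 0.34, Krt16 at 0.24, Sprr2h at 0.19, Nupr1 at 0.14 and Bnip3 at -0.0157, and the lists of inflammatory genes at 1.64, suprabasal differentiation at 0.55 and hypoxia at -0.0157. With bulge-like clusters alone Ereg stood at 0.59, Ovol1 at 0.27, Ly6d at 0.12, Cebpb at 0.11, Sprr2h at 0.0646, Spink5 at 0.0612, Sprr1a at 0.0600, Krt6a at 0.0284, Krt16 at 0.00338, wound-edge markers at 0.12 and suprabasal differentiation at 0.0713; by construction the cells outside these clusters, in both pools, are what was left out. Wound-edge markers stood at 0.0541 with equal weight per cell, which gave Sprr2h 0.10, and at 0.10 with no minimum CPM. Without fl/fl cells that had a Phgdh UMI Mt4 stood at -0.94, Krt1 at -0.53, interfollicular basal markers at -0.13 and G1/S genes at -0.12.

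In wounded fl/fl over +/+ at 3 days, Lce3c, Crct1 and Slpi stood at -1.36, -0.65 and -0.42 with at most 20% mitochondrial UMIs, and at -1.47, -0.66 and -0.0926 without fl/fl cells that had a Phgdh UMI. Amino acid transport stood at -0.0264 with equal weight per cell. Among male cells suprabasal differentiation stood at 0.0913 and inflammatory genes at 0.0530. At 5 days S100a9 stood at -0.0797, S100a8 at -0.0456 and suprabasal differentiation at 0.0420 with equal weight per cell. Without fl/fl cells that had a Phgdh UMI, suprabasal differentiation stood at 0.0440, G2/M genes at -0.0354 and cycling markers at -0.0441. Sebaceous markers stood at 0.11 with at most 5% mitochondrial UMIs and at 0.0245 among male cells. In the wound of +/+ cells at 5 days B2m stood at 0.11 with TMM factors and 0.0181 with equal weight per cell.

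Within cycling cells at 3 days, wound-edge genes stood at -0.00187 without fl/fl cells that had a Phgdh UMI, -0.0555 with stem cell genes left out of clustering, -0.15 with the hashtag share rule and -0.000187 among male cells. Interferon genes stood there at 0.17 (hashtag share rule) and 0.10 (male cells), G2/M genes at 0.0573 (male cells) and ATF4 targets at -0.00201 (hashtag share rule). Within cycling cells at 5 days, inflammatory genes stood at -0.30 without fl/fl cells that had a Phgdh UMI, heat shock genes at 0.0288 with the hashtag share rule and BMP genes at 0.0155 with the highest Scrublet scores removed. Within suprabasal cells at 5 days, the unfolded protein response stood at 0.0240 at Leiden resolution 0.5, and wound-edge genes at -0.0251 with the hashtag share rule and -0.00986 with stem cell genes left out. Within bulge-like cells at 5 days, immediate early genes stood at 0.11 with the hashtag share rule and 0.0273 with the highest Scrublet scores removed.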

Other observations

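The comparisons in this part were chosen after the data were seen and give values with no test. From 3 to 5 days the +/+ wound cells differed in differentiation and inflammation genes. The guidance receptor gene Robo1 stood at 90.1 CPM at 5 days and 21.0 CPM at 3 days (log2 fold 2.10), Krt10 at 2865 and 1178 CPM (1.28), Krt1 at 1.06 and the cathepsin gene Ctsc at 1.05. Lower at 5 days were Crct1 (27.0 against 157.9 CPM, -2.55), Mmp13 (20.6 against 84.9 CPM, -2.04), Lce3c (-1.94), the polyamine enzyme gene Odc1 (189.2 against 647.2 CPM, -1.77), S100a8 (-1.77) and S100a9 (-1.74). In fl/fl cells Krt10 (1.83), Krt1 (1.59) and Ctsc (1.37) were also higher at 5 than at 3 days, and Crct1 (-3.52), Lce3c (-3.21) and Klk7 (-2.85) lower. Mt4 stood at 249.5 CPM at 5 days and 24.0 CPM at 3 days in fl/fl (3.38), against 0.77 in +/+. Stem cell identity genes had a median of -1.42 from 3 to 5 days in fl/fl and -0.45 in +/+ cells, interferon genes of 0.74 and 0.62, and inflammatory genes of -0.49 and -0.75. At 3 days the highest fl/fl cell for each gene held much of the Lce3c and of the Crct1 UMIs, which bears on the fl/fl values of these genes. In +/+ cells at 3 days the 5 highest cells for each gene held 72.9% of the Lce3c and 49.9% of the Crct1 UMIs, which bears on the +/+ values.

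The fl/fl wound cells were also compared with unwounded fl/fl cells, with the same difference in sort gates. At 5 days Ccn2 stood at 4.4 against 1365 CPM (-8.26), Cck at -9.59 and Krt16 at 11401 against 587.0 CPM (4.28). Stem cell identity genes had medians of -2.38 (3 days) and -4.24 (5 days), ATF4 targets of 1.34 and 1.38, and all 18 aminoacyl-tRNA synthetase genes were higher at both days (1.05 and 1.12). Within the +/+ pool at 5 days female cells had more of the stem cell and upper follicle genes than male cells: Defb6 stood at 369.5 against 34.6 CPM (3.42), Lrig1 at 133.0 against 30.1 CPM (2.14), Krt79 at 511.2 against 128.0 CPM, and all 21 stem cell identity genes were higher (median 1.14). Female cells were lower in the EGF family ligand genes Ereg (8.1 against 92.4 CPM, -3.51), Areg (-1.53) and Hbegf (-1.37), in all 20 G2/M genes (median -0.73) and in all 15 glycolysis genes (median -0.58). Over all genes of at least 50 CPM, the log2 folds of female over male +/+ cells had an SD of 0.231 at 3 days and 0.419 at 5 days, and those of fl/fl over +/+ male cells an SD of 0.142 and 0.140. By size, 315 of 2856 genes were 1.5-fold or more apart between the sexes of +/+ cells at 5 days and 18 of 2790 between the genotypes among male cells. At 3 days these counts were 59 of 2886 and 13 of 2830. Sex, animal and wound are not separated in these values.

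Cluster 18, which no class named, held 68 +/+ and 82 fl/fl cells at 5 days, against 7 and 2 at 3 days. It expressed Thbs1 at 449.5 CPM against 31.6 CPM in other cells, and the chemokine genes Cxcl10 (224.7 against 19.2 CPM), Ccl2 (104.8 against 7.8 CPM) and Cxcl9 (71.1 against 3.0 CPM). Cluster 5 expressed Tspear (423.2 against 10.1 CPM), Sox6 (205.9 against 10.8 CPM) and Wnt16, and cluster 15 the envelope genes Lce3c (1732 against 2.8 CPM) and Crct1. Among stem cell genes below the level that the naming rule asks for, chosen after their values were seen, Lgr5 stood at 4.9 CPM in fl/fl and 19.98 CPM in +/+ cells at 5 days (-2.01) and Lhx2 at -1.74.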
